A study of Mus musculus with 39 samples.

How the data were processed

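The data are the deposited expression values of 39 Affymetrix mouse arrays, made from liver RNA of male B6C3F1 mice. Per the labels' protocols, the mice were 29 to 32 days old on arrival, had 5 days to acclimatise and received phenobarbital in drinking water at 0.05% (w/v). RNA was labelled with the 3' IVT Express procedure, and the submitters' processing notes name GCOS without a version. The deposited values are on a log2 scale, normalized between arrays by the authors. The method of normalization and the summarization of probes are not given in the sources used here. No value was changed, rescaled or imputed. The values never fall below 0 and array means are nearly equal, which was checked before any test.

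Samples were grouped by treatment and days of treatment as the labels give them, into 8 groups with 4 arrays in the day 1 controls and 5 in each other group. The treatment protocol in the labels mentions 28 days, whereas the durations given per sample go up to 91 days, and the durations per sample were used. The extraction protocol also names kidney, but the labels give liver for all 39 arrays. The labels give no batch, date or pairing. Day 28 control replicate 2 carries an identifier outside the range of the other arrays, which may mean a replaced or repeated array. Without it 1282 genes were higher and 2235 lower at day 28. Arrays carry no counts, so their number limits the precision of each value.

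Probe sets were paired with gene symbols by the annotation supplied with the values, in which 34958 of 45101 probe sets had 1 symbol, 932 had several and 9160 had none. The 64 control probe sets were left out of the genes, 13 of them with a symbol. Of the symbols, 34754 were matched by gene number to the reference table and 0 changed. Probe sets with several symbols were not used here. Each of the 18193 genes was represented by its probe set with the highest mean over all arrays, and a gene was tested when it lay above the median of the array on at least 4 arrays. This left 12580 genes, and 5613 did not pass.

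A linear model with 1 mean per group was fitted across the 39 arrays in limma 3.58.1 under R 4.3.3, with moderated variances that depend on mean signal (31 residual and 4.46 prior degrees of freedom). The comparisons were phenobarbital minus control at each of the 4 times, differences of that effect between times, an F test of the time dependence, and changes over time in controls. P-values are 2-sided and were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. Group measures per array were compared by exact 2-sided permutation tests.

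The 35 gene lists were written before the data were examined, as were the comparisons, the filter, the rule for named genes and most of the other settings tried. They hold 510 genes, of which 455 had a probe set of a single gene, 410 were tested and 2 were found through an older symbol. They cover CAR-responsive and conjugation enzymes, transporters, NRF2, proliferation, p53, the Dlk1-Dio3 cluster, DNA methylation, tumour markers, zonation, metabolism, acute phase, interferon, stress, clock, sex-biased genes and marker genes of 11 other sources of RNA and of hepatocytes. Lists were tested by camera with an inter-gene correlation of 0.01 and adjusted over 175 tests (35 lists in 5 comparisons), of which 27 were called. With an estimated correlation 12 calls held.

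Genes were named by a rule. For each day it took the 10 largest rises and the 10 largest falls among called genes whose treated arrays all lay on 1 side of all controls of that day. It also took the 10 smallest p-values of the F test, the 5 highest and 5 lowest interactions and changes in controls, and up to 4 called members of each list or, without a call, the 2 with the smallest p. Cyp2b10, Cyp2c55, Cyp3a11, Meg3, Rian, Cdkn1a, Mki67, Nr1i3, Ctnnb1 and the Tet and Dnmt genes were always named.

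The procedure was tested on simulated data with 12580 genes and the same groups. Of changes of 0.5 on the log2 scale it recovered 84%, 86%, 85% and 89% at days 1, 7, 28 and 91, and 97%, 95%, 97% and 98% of changes of 1. False calls made up 4.23%, 6.22%, 4.71% and 4.00% of the calls. The F test recovered 92% with 5.64% false. In a simulated set of lists the 1 raised list was called, and 0 of 100 unchanged lists were. The simulated genes varied independently of each other, so this does not test camera on lists whose genes are correlated. Far fewer genes were changed than were called in the data, and neither outlying arrays nor array-wide differences were simulated. The rates therefore need not hold for the gene calls in the data.

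The other settings tried were quantile normalization, centring on the array median, no filter, a stricter filter at the 75th percentile, the mean of all probe sets of a gene, leaving out probe sets that match several transcripts, no trend in the prior variance, a robust prior, array weights, only the arrays of the groups compared, fry and an estimated correlation for the lists, and leaving out each array in turn. Added after the data were seen were leaving out 4 arrays that stood apart, liver maturity (each array's mean over the male-biased list) as a covariate, the 3' minus 5' difference of the Actb and Gapdh control probe sets as a covariate, the mean of 18 bacterial spike-in hybridization control probe sets as a covariate, and list tests on the controls. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.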

Results

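Gene expression was measured in whole liver of male B6C3F1 mice that drank water with phenobarbital at 0.05% (w/v) or served as controls for 1, 7, 28 or 91 days. Phenobarbital activates the nuclear receptor CAR and promotes liver tumours in mice without damaging DNA. Each of the 39 arrays of the Affymetrix mouse GeneChip covered 45101 probe sets, and 12580 genes were tested. The controls of day 1 had 4 arrays and each of the other 7 groups had 5. The number of arrays limits the precision of each value. The first component of a principal component analysis held 39.2% of the variance between arrays and the second held 14.3%. Replicates of a group had Pearson correlations across all 45101 probe sets of 0.989 to 0.996, and neither probe sets nor genes are independent replicates. Values are log2 signals, fold changes are phenobarbital minus control on the log2 scale with their standard error (SE), and p-values are from limma with Benjamini-Hochberg adjustment. The labels do not state that each array came from a separate animal, so p-values measure the spread between these samples.

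The day 1 comparison asked how the liver responded to the first day of phenobarbital. Cyp2b10 (probe set 1451787_at), the classical target of CAR, rose from 7.83 ± 0.53 (SD, n = 4) to 14.04 ± 0.10 (SD, n = 5), a 74.0-fold increase (log2 fold change 6.21, SE 0.22, adjusted p = 1.33e-21). Cyp2c55 (1419582_at) rose by 3.99 (SE 0.23, adjusted p = 4.99e-15), and the glutathione transferase Gstm3 rose by 2.51 (SE 0.14, adjusted p = 2.98e-15). Among the list of CAR-responsive cytochromes P450 and phase I enzymes, 19 of 23 tested genes were higher and 0 lower. The counts adjusted over the list alone were also 19 and 0, the median log2 fold change was 0.92 and the camera adjusted p was 7.02e-16. Of 23 conjugation enzymes, 17 were higher, 17 also when adjusted over the list alone (median 0.64, adjusted p = 1.4e-13). Srxn1 rose by 1.55 (SE 0.10, adjusted p = 1.08e-13) and Nqo1 was 2.84-fold higher (SE 0.16 on the log2 scale, adjusted p = 1.34e-08). Their list of 13 NRF2 antioxidant genes had 6 higher and 1 lower, or 8 and 1 when adjusted over the list alone (median 0.51, adjusted p = 0.000182). That list had adjusted p = 0.0935 with an estimated correlation.

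Cell-cycle genes were higher after 1 day of phenobarbital. Of 24 DNA replication genes, 22 were higher and 1 lower, with the same counts when adjusted over the list alone (median 1.11, adjusted p = 3.73e-15). Of 24 mitosis genes, 21 were higher and 0 lower, again with the same counts when adjusted over the list alone (median 1.17, adjusted p = 1.42e-09). Adjusted p = 0.0935 with an estimated correlation for DNA replication, and adjusted p = 0.580 with an estimated correlation for mitosis. Without day 1 control replicate 4 the median was 0.982 for DNA replication and 0.705 for mitosis. Rrm2 rose by 1.85 (SE 0.36, adjusted p = 0.000158), Mcm5 by 1.55 (SE 0.28, adjusted p = 8.13e-05) and Cdk1 by 1.57 (SE 0.28, adjusted p = 5.25e-05). The proliferation marker Mki67 rose by 1.40 (SE 0.39, adjusted p = 0.0055). The call for Mki67 was lost without day 1 control replicate 4 (log2 fold change 0.86, adjusted p = 0.0686), which had 6.76 against at least 8.82 in the other 3 controls. It was also lost with liver maturity, the array's mean over male-biased genes, as a covariate (0.76, adjusted p = 0.0575). Gadd45b rose by 2.46 (SE 0.22, adjusted p = 3.56e-10), whereas the change of 0.67 in Cdkn1a was not called (SE 0.31, adjusted p = 0.0902).

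Serpina7 fell by 1.77 on the log2 scale (SE 0.33, adjusted p = 9.46e-05), Gprin3 by 1.82 (SE 0.31, adjusted p = 2.83e-05) and Hsd3b2 by 1.49 (SE 0.16, adjusted p = 1.59e-08). Ppargc1a fell by 1.39 (SE 0.31, adjusted p = 0.000782) and Fgf21 by 1.46 (SE 0.38, adjusted p = 0.00336). In total 1982 genes were higher and 2106 lower (130 and 58 of them by at least 2-fold). Higher genes made up 48.5% of the calls, 62.4% after quantile normalization and 63.0% with arrays centred on their median. Day 1 phenobarbital replicate 3 had a mean of 11.04 over 6 exocrine pancreas genes, against at most 6.96 in the other 4 treated arrays. That list was not called (median 1.18, 3 of 6 higher, adjusted p = 0.138). The mean of 18 spike-in hybridization control probe sets was 10.69 in treated arrays and 10.94 in controls (difference -0.25, exact permutation adjusted p = 0.0317 over 4 tests).

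**Figure D1:**
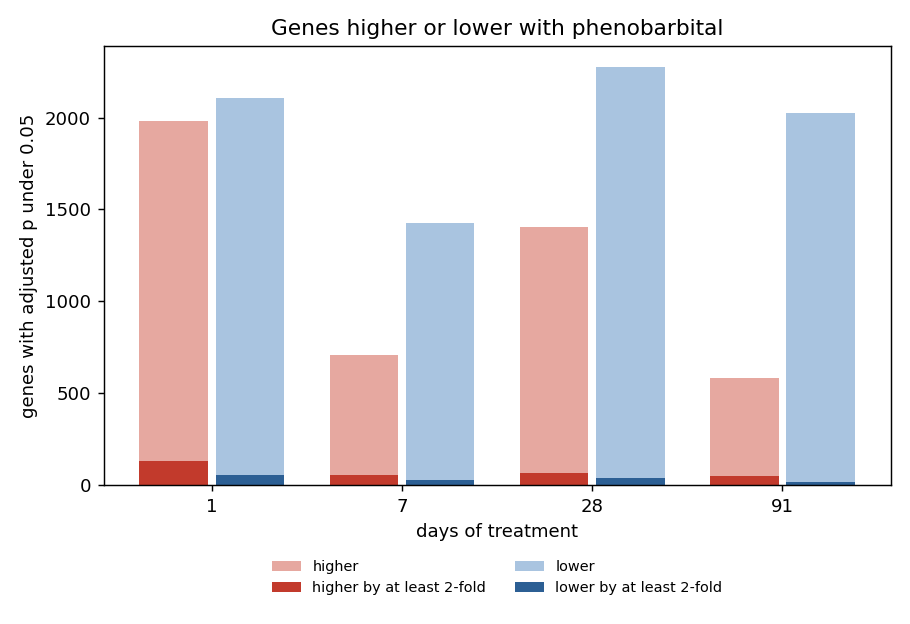
Number of genes higher (red) or lower (blue) with phenobarbital at limma adjusted p under 0.05 (y axis) against days of treatment (x axis), with the dark part of each bar for changes of at least 2-fold. At day 91, 581 genes were higher and 2023 lower, but 50 and 18 by at least 2-fold.

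After 7 days Cyp2b10 was 82.2-fold higher (log2 fold change 6.36, SE 0.21, adjusted p = 7.82e-23). The sulfotransferase Sult3a1 rose from 4.64 ± 0.75 (SD, n = 5) to 10.66 ± 1.64 (SD, n = 5), by 6.02 (SE 0.56, adjusted p = 5.27e-10). Cyp2c65 (1429994_s_at) rose by 3.86 (SE 0.33, adjusted p = 4.51e-11). Its control means at the 4 times (3.83 to 4.03) lay below the lower quartile of signals in each control array (4.37 to 4.48), so the size of its change is poorly determined at each time. Cyp2b13 rose by 4.09 (SE 0.56, adjusted p = 2.31e-06) and Pnliprp1 by 3.96 (SE 0.36, adjusted p = 3.24e-10). Cyp2b13 is also on the list of female-biased genes. The mean over male-biased genes at day 7 was 10.66 ± 0.95 in treated arrays and 11.40 ± 0.43 in controls (SD, n = 5 each). That difference was not called (exact permutation adjusted p = 0.302 over 8 tests), but a difference in liver maturity is not excluded. Dnaic1 fell by 2.72 (SE 0.22, adjusted p = 2.87e-11), Csad by 2.04 (SE 0.25, adjusted p = 3.01e-07) and Notum, a Wnt antagonist, by 0.88 (SE 0.13, adjusted p = 9.13e-06). Nr1i3, which encodes CAR itself, fell by 0.59 (SE 0.12, adjusted p = 0.000635), a call lost with the spike-in mean as a covariate (-0.34, adjusted p = 0.201). Of 23 phase I genes 19 were higher, 20 when adjusted over the list alone (median 0.71, adjusted p = 5.72e-41). Of 23 conjugation enzymes 19 were higher and 0 lower, or 21 and 1 when adjusted over the list alone (median 0.74, adjusted p = 6.01e-33). Of 12 hepatic transporters 6 were higher and 1 lower, or 7 and 1 when adjusted over the list alone (median 0.31, adjusted p = 1.06e-06), with Abcc3 up by 2.04 (SE 0.19, adjusted p = 3.24e-10).

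Some interferon-response genes were higher at day 7, with Ifit1 up by 0.82 (SE 0.17, adjusted p = 0.00107) and Rsad2 up by 0.83 (SE 0.18, adjusted p = 0.00165). Of the 15 genes of that list, 6 were higher and 0 lower, 11 and 0 when adjusted over the list alone (median 0.60, adjusted p = 3.08e-08). The list had adjusted p = 0.167 with an estimated correlation. Day 7 phenobarbital replicate 3, which also stood apart for neutrophil genes, had the highest interferon mean (9.57 against 8.52 to 9.06 in the other 4 treated arrays). Without it the median of the interferon list was 0.35 (adjusted p = 1.11e-06). Of 13 NRF2 antioxidant genes, 5 were higher, 5 also when adjusted over the list alone (median 0.18, adjusted p = 0.00219, and adjusted p = 0.206 with an estimated correlation). The NRF2 call was lost with the spike-in mean as a covariate (adjusted p = 0.108). In total 709 genes were higher and 1429 lower (57 and 26 by at least 2-fold). Higher genes made up 33.2% of the calls, 45.3% after quantile normalization and 51.4% with arrays centred on their median. The spike-in mean was 10.85 in treated arrays and 9.96 in controls at day 7, with no overlap (difference 0.89, exact permutation adjusted p = 0.0317). With it as a covariate 351 genes were higher and 500 lower, of which 518 were called in the same direction without it, and standard errors grew 1.43-fold.

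After 28 days Cyp2c65 rose from 3.83 ± 0.14 (SD, n = 5), below the lower quartile, to 10.76 ± 0.10 (SD, n = 5), by about 6.93 (SE 0.33, adjusted p = 3.79e-18), and Cyp2b10 rose by 6.90 (SE 0.21, adjusted p = 4.78e-24). Nebl (1438452_at) rose by 3.58 (SE 0.16, adjusted p = 7.52e-19). The imprinted non-coding RNA Meg3 (1439380_x_at) rose from 8.72 ± 0.29 (SD, n = 5) to 10.97 ± 0.21 (SD, n = 5), by 2.25 (SE 0.19, adjusted p = 4.61e-11). Rian (1452899_at), from the same Dlk1-Dio3 cluster, rose by 2.71 (SE 0.27, adjusted p = 4.5e-09). Of the 3 tested genes of that cluster 2 were higher, 2 also when adjusted over the list alone (median 2.25, adjusted p = 0.000127). Some probe sets of Meg3 (0.11, 0.20, 0.17 and 0.17) and Rian (-0.03 and 0.27) were not called at day 28, whereas the rest rose by 0.72 to 2.76. The cluster is known from related work on phenobarbital in mouse liver, so its list is not independent evidence of direction. Of 23 phase I genes 19 were higher and 1 lower, the same when adjusted over the list alone (median 0.63, adjusted p = 1.51e-21). Of 23 conjugation enzymes 18 were higher, 19 when adjusted over the list alone (median 0.66, adjusted p = 3.17e-18).

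Some lipid synthesis genes were higher and some fatty acid oxidation and fasting genes lower at day 28. The camera calls of their lists were lost with an estimated correlation. Thrsp rose by 1.42 (SE 0.19, adjusted p = 9.71e-07), Fasn by 0.98 (SE 0.21, adjusted p = 0.000884) and Elovl6 by 0.98 (SE 0.23, adjusted p = 0.00173). Of 16 lipogenesis genes 8 were higher, 9 when adjusted over the list alone (median 0.29, adjusted p = 0.000449, and adjusted p = 0.618 with an estimated correlation). Of 20 PPARA targets 11 were lower, 12 when adjusted over the list alone (median -0.28, adjusted p = 0.00173, and adjusted p = 0.685 with an estimated correlation). Irs2 fell by 1.15 (SE 0.23, adjusted p = 0.000323), and 5 of 10 fasting genes were lower, 6 when adjusted over the list alone (median -0.51, adjusted p = 0.0234, and adjusted p = 0.582 with an estimated correlation). The fasting list was not called without day 28 phenobarbital replicate 5 (adjusted p = 0.0632) or with the mean of all probe sets of a gene (adjusted p = 0.0563). Of 13 NRF2 genes 4 were higher and 1 lower, 5 and 1 when adjusted over the list alone (median 0.15, adjusted p = 0.0345, and adjusted p = 0.580 with an estimated correlation). The NRF2 call was lost without day 28 control replicate 5 (adjusted p = 0.0619), without day 28 phenobarbital replicate 1 (adjusted p = 0.0868), after quantile normalization (adjusted p = 0.103), with arrays centred on their median (adjusted p = 0.0542) and with array weights (adjusted p = 0.0659).

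In total 1403 genes were higher and 2276 lower at day 28 (69 and 38 by at least 2-fold). Higher genes made up 38.1% of the calls, 57.9% after quantile normalization and 53.4% with arrays centred on their median. The 3' minus 5' difference of the Actb and Gapdh control probe sets, a measure of RNA integrity and labelling, was 0.461 ± 0.0368 in treated arrays and 0.663 ± 0.108 in controls (SD, n = 5 each, exact permutation p = 0.00794, adjusted p = 0.0635 over 8 tests). With that difference as a covariate 411 genes were higher and 616 lower, of which 979 were called in the same direction without it. The difference did not overlap between the groups (0.422 to 0.503 in treated arrays, 0.516 to 0.806 in controls), so it went partly with treatment. Lost calls thus need not mean smaller effects. The spike-in mean was 10.86 in treated arrays and 11.21 in controls (difference -0.34, exact permutation adjusted p = 0.0423), and with it as a covariate 796 genes were higher and 1390 lower. Meg3, Rian, Nebl, Cyp2c65, Thrsp, Fasn and Irs2 kept their calls at day 28 with either covariate.

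After 91 days Cyp2c65, with controls again below the lower quartile, rose by about 7.13 (SE 0.33, adjusted p = 1.43e-18) and Cyp2b10 rose by 5.64 (SE 0.21, adjusted p = 2.32e-21). Meg3 rose from 8.43 ± 0.33 (SD, n = 5) to 11.45 ± 0.54 (SD, n = 5), by 3.02 (SE 0.19, adjusted p = 1.73e-14), and Rian rose by 3.02 (SE 0.27, adjusted p = 4.11e-10). Nebl rose by 4.33 (SE 0.16, adjusted p = 2.32e-21), Kcnk1 by 3.26 (SE 0.25, adjusted p = 7.19e-12), Abcc4 by 2.78 (SE 0.26, adjusted p = 9.08e-10) and E-cadherin (Cdh1) by 1.33 (SE 0.12, adjusted p = 4.76e-10). Obp2a, formerly Lcn13, fell by 2.25 (SE 0.26, adjusted p = 1.12e-07), Csad by 1.83 (SE 0.25, adjusted p = 3.23e-06) and Cyp2c39 by 1.72 (SE 0.28, adjusted p = 5.73e-05). All 3 tested genes of the Dlk1-Dio3 cluster were higher, 3 also when adjusted over the list alone (median 3.02, adjusted p = 3.76e-09). Dlk1 itself did not pass the filter, and its 2 probe sets were lower (-0.28 and -0.33, adjusted p = 0.0293 and 0.0137 over all probe sets). Of the Meg3 probe sets, 2 differed by 0.06 and 0.04 and were not called. Some other probe sets rose less (Meg3 by 0.35 and 0.39, Rian by 0.51 and 0.71), whereas the rest rose by 1.14 to 3.36. Of 23 phase I genes 16 were higher and 2 lower, 17 and 2 when adjusted over the list alone (median 0.39, adjusted p = 7.27e-26). Of 23 conjugation enzymes 14 were higher, 16 when adjusted over the list alone (median 0.35, adjusted p = 1.04e-17).

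Among other lists at day 91, 8 of 20 PPARA targets were lower, 12 when adjusted over the list alone (median -0.29, adjusted p = 0.00375, and adjusted p = 0.742 with an estimated correlation). That call was lost without day 91 control replicate 3 (adjusted p = 0.0589). Of 12 transporters 3 were higher and 1 lower, with the same counts when adjusted over the list alone (median 0.03, adjusted p = 0.0254, and adjusted p = 0.210 with an estimated correlation). The transporter call was lost after quantile normalization (adjusted p = 0.102) and without probe sets that match several transcripts (adjusted p = 0.103). In total 581 genes were higher and 2023 lower (50 and 18 by at least 2-fold). Without day 91 control replicate 5, 378 genes were higher. Array weights gave 1017 higher and 3040 lower, and arrays centred on their median gave 792 and 1076. Higher genes made up 22.3% of the calls, 38.9% after quantile normalization and 42.4% with arrays centred on their median.

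**Figure D2:**
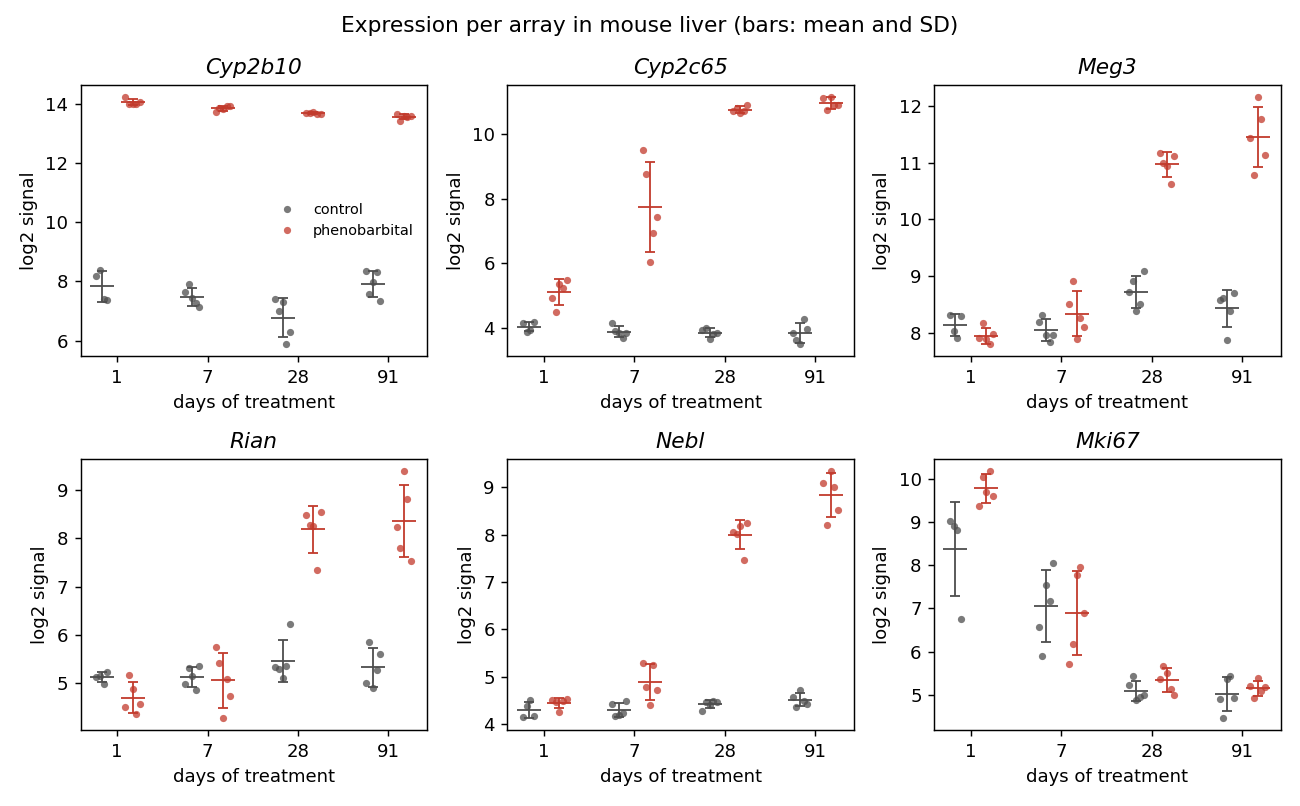
Log2 signal (y axis) of Cyp2b10, Cyp2c65, Meg3, Rian, Nebl and Mki67 on each array (points) at 1, 7, 28 and 91 days (x axis) in control and phenobarbital groups, with bars for the mean and SD. Cyp2b10 was high in treated arrays at each time, whereas Meg3, Rian and Nebl were at least 4.75-fold higher at days 28 and 91 and Nebl by 0.59 on the log2 scale at day 7.

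A shared response was asked for by comparing the calls of the 4 times. At all 4 times 135 genes were higher, among them Cyp2b10, Cyp2c55, Gstm3, Abcc4 and Gadd45b, against 0.575 expected if the times were independent. For 34 of them the mean change was at least 2-fold. At all 4 times 91 genes were lower, among them Csad and Dnase2a, against 6.96 expected. All times shared 1 estimate of the spread per gene, and treated array means were lower at each time. Shared calls can thus exceed the expected counts, here and for pairs of times, without a shared response. The count of lower genes was 42 with arrays centred on their median, 55 after quantile normalization, 59 with the 3' minus 5' difference and 49 with the spike-in mean as a covariate, and 240 genes were higher without a filter on dim genes. Expected counts were not worked out for these settings. Days 1 and 28 shared 800 higher and 1257 lower genes (221 and 381 expected), and 37 genes changed in opposite directions. Days 7 and 91 shared 270 higher and 683 lower genes (32.7 and 230 expected), and 7 were opposite. Between days 1 and 91, 213 genes were higher at both (91.5 expected), 270 were lower at both (339 expected) and 328 were opposite (416 expected). Fold changes correlated across genes with r = 0.659 between days 1 and 28, 0.642 between days 7 and 91, 0.486 between days 7 and 28, 0.405 between days 28 and 91, 0.359 between days 1 and 7 and 0.171 between days 1 and 91. Genes are not independent replicates, so these correlations carry no p-value.

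The next comparison asked which effects of phenobarbital differed between times. Duration of treatment went together with age and with the arrays of each day. A response that grew or faded with treatment therefore cannot be told from a different response of older livers. The effect on Nebl was 4.18 larger on the log2 scale at day 91 than at day 1 (SE 0.23, adjusted p = 2.06e-15), and Nebl had the smallest interaction p of all genes tested (F test, adjusted p = 5.5e-17). The effect on Cyp2c65 was larger by about 6.08 (SE 0.47, adjusted p = 4.7e-11), a size limited by its control signals below the lower quartile, on Meg3 by 3.21 (SE 0.27, adjusted p = 4.38e-10), on Rian by 3.44 (SE 0.40, adjusted p = 4.63e-07) and on Gm10419 (1436265_at) by 3.19 (SE 0.32, adjusted p = 3.33e-08). Nebl and Gm10419 also had control means below the lower quartile at days 1 and 7. At days 1 and 7 Meg3 differed by -0.19 and 0.28 and Rian by -0.42 and -0.07, none of them called. Another Rian probe set of similar mean signal (5.89 against 5.94) differed by 0.43 at day 1 and by 0.72 at day 7, the latter with adjusted p = 0.0366 over all probe sets, so a rise of Rian by day 7 was not excluded. Mirg, the third tested gene of the cluster, fell by 0.40 at day 1 (adjusted p = 0.00148), a call lost with the mean of all its probe sets (-0.14). For the 3 tested genes of the Dlk1-Dio3 cluster the median interaction was 3.21, with 3 higher and 3 when adjusted over the list alone (adjusted p = 1.8e-06).

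Proliferation genes moved the other way. The interaction at day 91 minus day 1 was -2.60 for Pbk (SE 0.42, adjusted p = 5.57e-05), -1.83 for Tcf19 (SE 0.32, adjusted p = 0.000135) and -1.81 for Mcm5 (SE 0.39, adjusted p = 0.00093), whereas the interaction of -1.26 for Mki67 was not called (SE 0.53, adjusted p = 0.0682) except with the spike-in mean as a covariate or without day 1 control replicate 1. Of 24 DNA replication genes 20 were lower, 21 when adjusted over the list alone (median -1.27, adjusted p = 1.21e-10, and adjusted p = 0.217 with an estimated correlation). Of 24 mitosis genes 15 were lower, 21 when adjusted over the list alone (median -1.21, adjusted p = 2.25e-06, and adjusted p = 0.639 with an estimated correlation). Array means of the mitosis list at day 91 were 5.28 to 5.67 in controls and 5.23 to 5.42 in treated arrays. These lay below the array medians (5.69 to 5.78), so little signal was left to differ. Both interactions were close in size to the day 1 medians (1.11 and 1.17), and that of mitosis fell to 0.705 without day 1 control replicate 4. Obp2a had an interaction of -2.24 (SE 0.38, adjusted p = 8.48e-05) and Srxn1 of -1.19 (SE 0.14, adjusted p = 4.68e-07).

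Of 12 periportal genes 6 had a higher interaction and 1 a lower, with the same counts when adjusted over the list alone (median 0.20, adjusted p = 0.0254, and adjusted p = 0.186 with an estimated correlation). Cdh1 of that list had an interaction of 1.48 (SE 0.18, adjusted p = 6.93e-07). The periportal call was lost without day 1 control replicate 4 (adjusted p = 0.0566), without day 1 phenobarbital replicate 3 (adjusted p = 0.0538), without the 4 arrays that stood apart (adjusted p = 0.0686) and with a stricter filter (adjusted p = 0.0643). Of 10 male-biased genes 1 had a higher interaction, 0 when adjusted over the list alone (median 0.71, camera adjusted p = 0.0221, and adjusted p = 0.792 with an estimated correlation). The male-biased call was lost without day 1 control replicate 1 (adjusted p = 0.108), day 1 control replicate 4 (adjusted p = 0.157) or day 91 control replicate 3 (adjusted p = 0.0571), without the 4 arrays that stood apart (adjusted p = 0.114), with array weights (adjusted p = 0.319), by fry (adjusted p = 0.219) and with a stricter filter (adjusted p = 0.0583). It was also lost with liver maturity as a covariate (0.089, adjusted p = 0.692), which is the mean of this same list and so no separate test of it.

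The effect was time-dependent for 4415 genes (35.1% of those tested, F test). At day 91 minus day 1 it was higher for 1391 genes and lower for 2437, of which 122 and 128 by at least 2-fold. The counts were 1026 higher and 1650 lower at day 7 minus day 1, 72 and 337 at day 28 minus day 1, 752 and 727 at day 28 minus day 7, and 1149 and 1578 at day 91 minus day 28. At day 28 minus day 7 they were 387 and 391 without day 7 control replicate 1, 393 and 421 without day 28 control replicate 4, and 1309 and 1119 without day 28 control replicate 5. In the same comparison 473 genes were lower without day 7 control replicate 2, 472 were lower without day 28 control replicate 3 and 495 were higher without day 28 phenobarbital replicate 2. At day 91 minus day 28 they were 755 and 981 without day 28 control replicate 4, and 739 were higher without day 91 control replicate 5. Array weights gave more calls in both directions at day 28 minus day 7 and at day 91 minus day 28. With the 3' minus 5' difference as a covariate limma called 58 higher and 46 lower genes at day 28 minus day 7, and 0 genes at day 91 minus day 28, where 1775 had an unadjusted p under 0.05. That covariate went partly with treatment at day 28. Day 91 control replicate 1 (0.870) also lay far from the other controls of that day (0.445 to 0.557). Calls lost with it thus need not mean smaller differences. With the spike-in mean as a covariate 1951 genes had a time-dependent effect. It was higher for 720 and lower for 1509 at day 91 minus day 1, for 58 and 348 at day 7 minus day 1, for 1 and 0 at day 28 minus day 7, and for 60 and 75 at day 91 minus day 28.

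**Figure D3:**
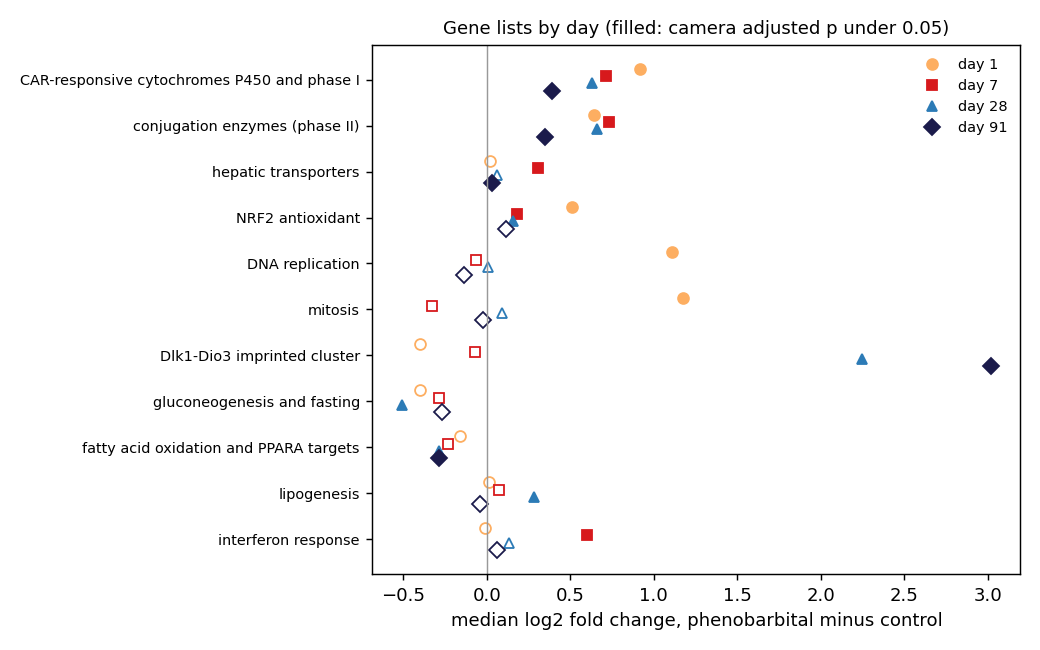
Median log2 fold change (x axis) of each gene list with a camera call on at least 1 day (y axis), with markers for days 1, 7, 28 and 91 and filled markers for adjusted p under 0.05. The lists of DNA replication and mitosis had medians of 1.11 and 1.17 at day 1, and the Dlk1-Dio3 cluster had 2.25 at day 28 and 3.02 at day 91.

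The controls alone gave the change between time points, in which age, kill and array handling go together, as the background of the effects above. Nox4 rose from 5.76 ± 1.56 (SD, n = 4) at day 1 to 10.06 ± 0.35 (SD, n = 5) at day 91, by 4.30 (SE 0.57, adjusted p = 3.54e-07), and Snhg11 rose by 3.15 (SE 0.18, adjusted p = 1.47e-15). Tff3 fell by 4.57 (SE 0.43, adjusted p = 3.33e-10), Lpl fell by 3.68 (SE 0.15, adjusted p = 2.72e-19) and the mitosis gene Birc5 fell by 3.86 (SE 0.45, adjusted p = 3.43e-08), to a mean of 4.35 below the lower quartile of signals. Of the 12580 genes tested, 8303 (66.0%) changed over time in controls, and 2476 were higher and 2082 lower at day 91 than at day 1. Against day 1, 2373 genes were higher and 2057 lower at day 7, and 1092 and 1484 at day 28, so the counts did not grow steadily with time. With the spike-in mean as a covariate 5034 genes changed over time in controls. Lists were tested on the controls by a choice made after the data were seen. Of 24 mitosis genes 21 were lower, 21 also when adjusted over the list alone (median -1.85, adjusted p = 6.74e-16, and adjusted p = 0.172 with an estimated correlation). Of 24 DNA replication genes 1 was higher and 19 lower, with the same counts when adjusted over the list alone (median -0.82, adjusted p = 7.99e-10, and adjusted p = 0.172 with an estimated correlation). Of 11 stellate cell genes 8 were lower, 9 when adjusted over the list alone (median -0.66, adjusted p = 1.53e-08), a call that held with an estimated correlation (adjusted p = 0.0472). Of 10 male-biased genes 6 were higher, 6 also when adjusted over the list alone (mean 1.55, adjusted p = 0.000138, and adjusted p = 0.416 with an estimated correlation). Controls also had lower medians at day 91 for Kupffer cell genes (-0.72, 12 of 12 lower), interferon genes (-0.65, 12 of 15 lower) and cholesterol synthesis genes (-0.51, 13 of 17 lower). For these lists the adjusted p with an estimated correlation was 0.319, 0.172 and 0.238. With liver maturity as a covariate 1246 genes were higher and 981 lower in controls at day 91 than at day 1.

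Because the series concerned 5-hydroxymethylcytosine, the genes that write and oxidise DNA methylation were compared. Dnmt1 (1422946_a_at) rose by 0.64 at day 1, from 8.63 ± 0.19 (SD, n = 4) to 9.28 ± 0.22 (SD, n = 5; SE 0.10, adjusted p = 1.35e-05), and its interaction at day 91 minus day 1 was -0.82 (SE 0.14, adjusted p = 0.000105). Uhrf1, which recruits Dnmt1 to replicating DNA, rose by 1.62 at day 1 (SE 0.16, adjusted p = 4.94e-09). Dnmt3a (1423063_at) fell by 0.40 at day 1 (SE 0.10, adjusted p = 0.00189), by 0.44 at day 7 (SE 0.09, adjusted p = 0.0011) and by 0.48 at day 28 (SE 0.09, adjusted p = 0.00023), and differed by 0.00 at day 91 (SE 0.09, adjusted p = 0.99). The interaction of Dnmt3a at day 91 minus day 1 was 0.40 (adjusted p = 0.0227), with the call lost without day 91 control replicate 2 (0.35, adjusted p = 0.0520) or day 91 phenobarbital replicate 4 (0.35, adjusted p = 0.0510), and with liver maturity (0.36, adjusted p = 0.0508), the 3' minus 5' difference (0.29, adjusted p = 0.116) or the spike-in mean (0.30, adjusted p = 0.125) as a covariate. Tet2 (1455300_at) fell by 0.32 at day 1 (SE 0.10, adjusted p = 0.0196). That call was lost without day 1 control replicate 2 (-0.20, adjusted p = 0.152), day 1 control replicate 3 (-0.27, adjusted p = 0.0759) or day 1 phenobarbital replicate 4 (-0.28, adjusted p = 0.0547), with the 3' minus 5' difference as a covariate (-0.28, adjusted p = 0.0552) and with the 9 arrays of day 1 alone (adjusted p = 0.0802). Tet3 and Dnmt3b were not called at any time, and Tet1 and Dnmt3l did not pass the filter. The list of 9 tested genes of the methylation machinery was not called at any time, with the smallest adjusted p of 0.227 at day 91 (1 higher and 0 lower, 0 and 0 when adjusted over the list alone). In controls 5 of its 9 genes were lower at day 91 than at day 1, 5 also when adjusted over the list alone (median -0.34, adjusted p = 0.011, and adjusted p = 0.0775 with an estimated correlation).

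Cyp3a11 and other genes always named showed small or uneven changes. Cyp3a11, with a control mean of 14.51 at day 1 where the highest signals of the arrays were 15.03 to 15.12, lay close to the upper end of the scale, so its changes are poorly determined. It rose by 0.12 (adjusted p = 0.0085), 0.37, 0.15 and 0.15 at the 4 times in turn. Its day 1 call was lost without day 1 control replicate 3 (0.09, adjusted p = 0.0601) and without the 4 arrays that stood apart (0.10, adjusted p = 0.0605). Nr1i3 had a change of 0.31 at day 1 that was not called (SE 0.13, adjusted p = 0.0578) and fell by 0.50 at day 91 (SE 0.12, adjusted p = 0.0032), with an interaction of -0.81 (SE 0.17, adjusted p = 0.000856). Ctnnb1 fell by 0.14 at day 28 (SE 0.04, adjusted p = 0.0103), but differed by 0.13 with the mean of all its probe sets (adjusted p = 0.159). Of its 3 probe sets 1 was called lower (-0.14) and 1 higher (0.38), so its direction at day 28 stays open. That call was lost with arrays centred on their median (-0.11, adjusted p = 0.0753) and with the 3' minus 5' difference (-0.13, adjusted p = 0.113) or the spike-in mean (-0.12, adjusted p = 0.0606) as a covariate. Of the 16 Wnt and perivenous genes, 1 was higher and 7 lower at day 1, with the same counts when adjusted over the list alone (median -0.12, adjusted p = 0.0820), which missed the threshold. Lgr5 of that list fell by 1.13 at day 1 (SE 0.20, adjusted p = 5.71e-05).

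The other lists were not called by camera on any day or for the interaction. The smallest adjusted p was 0.0501 for cholesterol synthesis (17 genes, day 91) and for female-biased genes (9 genes, day 7), 0.118 for the unfolded protein response (17 genes, day 28), 0.154 for oncofetal and liver tumour markers (10 genes, day 1) and 0.190 for bile acid synthesis (10 genes, day 7). It was 0.195 for the circadian clock (16 genes, interaction), 0.235 for p53 targets (13 genes, day 91) and 0.365 for acute phase genes (20 genes, interaction). Ccn4, formerly Wisp1, rose by 1.82 at day 91 within the tumour markers (SE 0.18, adjusted p = 1.64e-09), whereas Obp2a of the same list fell, as given above. Orm3 rose by 1.84 within the acute phase genes (SE 0.18, adjusted p = 1.59e-09). Among cell types the smallest adjusted p was 0.0579 for sinusoidal endothelium (12 genes, day 7), 0.154 for hepatocytes (13 genes, day 91), 0.154 for stellate cells (11 genes, day 28) and 0.645 for Kupffer cells (12 genes, day 7). It was 0.473 for cholangiocytes (5 genes, day 91), 0.365 for T and NK cells (5 genes, day 91) and 0.227 for B and plasma cells (5 genes, day 28), in which Ighm rose by 1.63 (SE 0.26, adjusted p = 2.09e-05). It was 0.918 for neutrophils (2 genes, day 91), 0.473 for erythroid cells (2 genes, day 1), 0.375 for adipocytes (2 genes, day 7) and 0.245 for kidney (3 genes, day 7).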

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

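The tests of the mitosis genes against liver maturity and against a single array, all tests on spike-in controls, the splits at day 28 minus day 1 and of controls at days 7 and 28 minus day 1, and the alternatives with liver maturity, the 3' minus 5' difference or the spike-in mean as a covariate, were chosen after the result was seen.

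DNA replication and mitosis genes were higher with phenobarbital at day 1. For DNA replication the effect on the array means was 1.00 and stayed at 0.776 (95% interval 0.564 to 0.988) with liver maturity as a covariate. Without day 1 control replicate 4 its median was 0.982, with a lower bound of 0.595 for the effect on the array means. Neither maturity as that covariate measures it nor that 1 array thus explains it alone. The covariate, a mean over male-biased genes, is an imperfect measure of maturity, so less mature treated livers are not excluded. For mitosis the same values were 0.721 (0.290 to 1.15) and a median of 0.705 (lower bound 0.266), whose intervals reach below 0.548, and both explanations stay open there. A response of the liver to the first day of phenobarbital is the biological candidate explanation and was tested by the group comparison alone.

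At day 91, 22.3% of the calls were higher, and leaving out 1 array gave 19.9% to 25.9%. The share was 42.4% with arrays centred on their median, past the bound of 40% set for a shift common to most genes, and 38.9% after quantile normalization, between the bounds set for a brightness-dependent bias, which stays open. Centring removes such a shift whether the authors' normalization left it or treatment caused it, so the share does not tell its source. Spike-in hybridization controls, meant to be equal in each sample, differed by 0.223 (95% interval -0.423 to 0.870), an interval that holds both 0 and the median log2 fold change of all genes (-0.066). Array means were lower with phenobarbital at each of the 4 times (6.229 against 6.253 at day 91, exact permutation p = 0.00794). From these values a shift left by the normalization and an effect of treatment on most genes cannot be told apart.

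Fold changes of days 1 and 28 were closer to each other (r = 0.659 across genes, which are not independent replicates) than to those of days 7 and 91. With the 3' minus 5' difference as a covariate r was 0.596, against 0.579 between days 7 and 28 and 0.590 between days 28 and 91. With the spike-in mean as a covariate r was 0.628, above the bound of 0.60 set to exclude that cause, but days 7 and 28 then had 0.643 and days 7 and 91 had 0.481, so the pattern was not kept. RNA integrity, labelling and hybridization stay open, as does feeding, for which the fasting list had a median of -0.066 for days 1 and 28 minus days 7 and 91, above the bound of -0.1 set beforehand, over 10 genes that went both ways (-1.81 to 0.23). In that comparison 2992 genes were higher and 1929 lower, and a biological difference between these times was not tested.

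The effect of phenobarbital differed between times by the test of the interaction. It differed for 3828 genes at day 91 minus day 1, 2676 at day 7 minus day 1, 409 at day 28 minus day 1, 1479 at day 28 minus day 7, 2727 at day 91 minus day 28, and 4415 by the F test. With the 3' minus 5' difference as a covariate the counts were 2335 at day 91 minus day 1, 104 at day 28 minus day 7, 0 at day 91 minus day 28 (with 1775 at an unadjusted p under 0.05) and 2253 by the F test. With the spike-in mean as a covariate they were 2229 at day 91 minus day 1, 406 at day 7 minus day 1, 1 at day 28 minus day 7 (with 594 at an unadjusted p under 0.05, where 5% of the genes tested is 629), 135 at day 91 minus day 28 and 1951 by the F test. The 1 gene still called at day 28 minus day 7 had a limma adjusted p of 4.3e-08. For the other genes a difference between the effects of days 7 and 28 cannot be told from one in hybridization. The spike-in covariate also raised standard errors at day 7 by 1.43-fold, so lost calls need not mean smaller differences. The same holds for calls lost with the 3' minus 5' difference, which did not overlap between treated and control arrays at day 28. Among lists the median interaction at day 91 minus day 1 was -1.27 for DNA replication, -1.21 for mitosis, 3.21 for the Dlk1-Dio3 cluster, 0.20 for periportal genes and 0.71 for male-biased genes.

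In all but 2 comparisons only the real split, 1 of 100 splits of the same arrays, gave as many calls. In those 2 it was 2 and 3 of 100. For each day alone and for controls over time, calls by chance are thus unlikely. The splits for differences between times and for calls at all 4 times also broke up the treatment effect itself. They therefore cannot judge whether a difference between times arose by chance. The splits of controls mixed all 4 days, so they cannot judge 1 pair of days alone. The real split gave 4088 calls at day 1 and the highest other 2422, and the values were 2138 and 392 at day 7, 3679 and 2624 at day 28, and 2604 and 1705 at day 91. Those highest other splits had 1 or 2 arrays out of place, counted over both groups of the day, so they were close to the real split. Splits with at least 3 out of place gave at most 2, 170, 2 and 23. The real and highest other values were 4415 and 581 for the F test, 3828 and 713 at day 91 minus day 1, 2676 and 1073 at day 7 minus day 1, 409 and 1019 at day 28 minus day 1 (2 of 100), 1479 and 984 at day 28 minus day 7, and 2727 and 363 at day 91 minus day 28. They were 226 and 0 for genes called at all 4 times, 8303 and 2660 for controls over time, 4558 and 3085 for controls at day 91 minus day 1, 4430 and 1665 at day 7 minus day 1, and 2576 and 3480 at day 28 minus day 1 (3 of 100). What the splits with more calls than the real one had in common was not tested.

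Some arrays lay far from the rest of their group, by a rule that picks about 1 in 20 groups by chance. Among list means this held for 21 of 280 groups (14 by chance), among the genes always named for 5 of 112 (5.6 by chance) and among other named genes for 125 of 2064 (103 by chance).

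Day 1 phenobarbital replicate 3 had 11.04 for exocrine pancreas (nearest other 6.96) and 11.68 for cholesterol synthesis (11.48). Day 1 control replicate 4 had 6.21 for mitosis (7.62), 9.06 for Wnt and perivenous genes (9.36) and 6.76 for Mki67 (8.82). Day 7 phenobarbital replicate 3 had 11.21 for neutrophils (5.90) and 6.57 for T and NK cells (6.18), and day 7 control replicate 4 had 13.23 for acute phase (11.67) and 12.05 for periportal genes (11.91).

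Other arrays apart at day 1 were control replicate 1 for the clock (8.05), control replicate 2 for erythroid cells (7.45), phenobarbital replicate 2 for cholangiocytes (6.60) and phenobarbital replicate 5 for p53 targets (8.27). At day 7 they were control replicate 2 for cholesterol synthesis (10.79), phenobarbital replicate 2 for bile acid synthesis (11.78) and phenobarbital replicate 4 for Wnt and perivenous genes (9.002). At day 28 they were phenobarbital replicate 3 for interferon (8.09), phenobarbital replicate 5 for fasting (10.04), phenobarbital replicate 4 for Cyp2c55 (13.55) and Rian (7.34), control replicate 5 for Rian (6.23) and control replicate 1 for Tet2 (8.83). At day 91 they were control replicate 1 for p53 targets (7.80), control replicate 3 for NRF2 (10.19), phenobarbital replicate 4 for Kupffer cells (8.79) and phenobarbital replicate 5 for B and plasma cells (6.74).

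Probe sets without a gene symbol, which no comparison above used, also differed between treated and control arrays. Of 2887 tested, 982 were called at day 1 (282 higher and 700 lower), 378 at day 7 (112 and 266), 847 at day 28 (261 and 586) and 287 at day 91 (110 and 177). The probe set 1443137_at was higher by 6.02, 5.93, 5.15 and 5.52 at the 4 times, and 1423556_at by 3.62, 3.75, 3.22 and 2.11.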

How the results depend on the processing

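The 4 arrays left out together and the 3 covariates were chosen after the data were seen. Of 441 called values of named genes, quantile normalization kept the direction and call of 416, median centring of 397, array weights of 425, liver maturity of 405, the 3' minus 5' difference of 365 and the spike-in mean of 333. Leaving out 1 array kept 4354 of 4910. Pseudocounts were not run, because the values were already on a log2 scale. No paired analysis was possible because the labels carry no replicate numbers that link treated and control arrays. The 5613 genes not tested did not lie above the array median on at least 4 arrays, and background signal was not measured. Where no reason is given below, the cause was not tested.

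Quantile normalization gave 2350 higher genes at day 28, 1221 lower at day 91 and 55 lower at all 4 times. Median centring gave 879 lower at day 7, 1076 lower at day 91, 42 lower at all 4 times and 0.000814 for Apoa2 at day 91, reversed. Without a filter, with more genes tested, 2164 were higher at day 28, 966 at day 91 and 240 at all 4 times. With a stricter filter, with fewer tested, 1245 were lower at day 91. The mean of all probe sets reversed Fads1 at day 1 (-0.18) and Ctnnb1 at day 1 (0.020), day 28 (0.13) and day 91 minus day 1 (-0.20). Without _s_at and _x_at probe sets Lss was reversed at day 1 (-0.049) and day 28 (-0.018), and Epcam at day 28 (-0.18). Array weights gave 1017 higher and 3040 lower at day 91, 1629 and 1284 at day 28 minus day 7, and 1908 and 2909 at day 91 minus day 28. Liver maturity gave 1246 and 981 in controls at day 91 minus day 1.

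The 3' minus 5' difference gave 411 and 616 at day 28, 797 and 1538 at day 91 minus day 1, 58 and 46 at day 28 minus day 7, 2253 by the F test and 59 lower at all 4 times. At day 91 minus day 28 limma then gave 0 higher and 0 lower, with 1775 genes at an unadjusted p under 0.05. The spike-in mean gave 351 and 500 at day 7, 796 and 1390 at day 28, 720 and 1509 at day 91 minus day 1, 58 and 348 at day 7 minus day 1, 1 and 0 at day 28 minus day 7, 60 and 75 at day 91 minus day 28, 1951 by the F test, 5034 in controls over time and 49 lower at all 4 times. Of 27 list calls, 12 held with an estimated correlation and 26 by fry, which made 51 calls in 175 tests but asks whether a list changed at all, not whether it changed more than other genes.

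Leaving out 1 array gave 378 to 694 higher at day 91, 387 to 1309 higher and 391 to 1119 lower at day 28 minus day 7, and 739 to 1463 higher and 981 to 2166 lower at day 91 minus day 28. The lowest values came without day 91 control replicate 5 (378 and 739), day 7 control replicate 1 (387 and 391) and day 28 control replicate 4 (981), and the highest at day 28 minus day 7 without day 28 control replicate 5.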

Other observations

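The genes below were chosen after their values were seen, so all comparisons of this part were chosen after the result was seen.

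The heat shock genes Hspa1a, Dnajb1 and Bag3 were higher with phenobarbital at day 28, and no list of such genes was tested. Hspa1a rose by 2.27 (adjusted p = 0.00092), Dnajb1 by 1.25 (adjusted p = 0.0016) and Bag3 by 1.15 (adjusted p = 2.7e-05), and none of these 3 was called at the other times. With the 3' minus 5' difference as a covariate, which differed by -0.202 at day 28 (exact permutation adjusted p = 0.0635), they rose by 2.21 (adjusted p = 0.0209), 1.22 (adjusted p = 0.0297) and 0.87 (adjusted p = 0.00883). The interaction by the F test was called for Bag3 (adjusted p = 0.0019) and not for Hspa1a (0.081) or Dnajb1 (0.072). In controls Hspa1a was higher by 3.27 and Hspb1 by 2.74 at day 91 than at day 1, and Hspb1 was not called with phenobarbital at any time.

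Malat1 fell by 1.05 at day 1 (adjusted p = 0.0011) and by 1.00 at day 28 (adjusted p = 0.0013), and rose by 0.63 at day 7 (adjusted p = 0.049). Prox1 fell by 1.44 at day 1 (adjusted p = 0.00062) and by 1.68 at day 28 (adjusted p = 8.2e-05), with changes of 0.69 at day 7 and 0.22 at day 91 that were not called. The 3' minus 5' difference of treated and control arrays at day 1 was -0.0944 (exact permutation p = 0.0476, adjusted p = 0.190). At day 28 it was -0.202, with no overlap (exact permutation p = 0.00794, adjusted p = 0.0635). That p is the smallest possible with these arrays and could not pass 0.05 alone after adjustment over 8 tests. A difference in RNA integrity or labelling is thus not excluded at either day. With the 3' minus 5' difference as a covariate Malat1 fell by 0.95 at day 1 (adjusted p = 0.00469). It differed by -0.79 at day 28 (adjusted p = 0.0642), no longer called, whereas Prox1 fell by 1.32 (adjusted p = 0.0027) and 1.43 (adjusted p = 0.0105). With the spike-in mean as a covariate Malat1 fell by 0.91 at day 1 (adjusted p = 0.00407) and 0.82 at day 28 (adjusted p = 0.0133) and Prox1 by 1.27 (adjusted p = 0.00232) and 1.45 (adjusted p = 0.00114), whereas the change of 0.16 in Malat1 at day 7 was not called (adjusted p = 0.808).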
